A study of Mus musculus with 24 samples.

How the data were processed

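RNA was measured in ileum and liver of mice after 75% small bowel resection, in 24 libraries: 2 tissues, 2 genotypes (Abca1 floxed, with or without Villin-Cre) and 2 treatments (GW3965 at 1 mg/kg in 0.5% carboxymethyl cellulose, or vehicle), with 3 libraries in each of 8 groups. All groups had been operated on, and no group without resection is part of the comparisons. Group and replicate number come from the sample labels. Per the labels' protocols, RNA was prepared with RNeasy kits, ribosomal RNA was removed with an RNase H method (RiboErase), and libraries were made with random hexamers and read in pairs of 150 bases on a NovaSeq. Per the submitters' processing notes, bcl2fastq, STAR 2.5.1a, Subread, featureCounts 1.4.6-p5 and the GRCm38 genome build were used. The annotation release, the strand setting of the counting and the formula of the log transform are not given in the sources used here.

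The authors deposited a table of log2 expression values for each tissue, with 40757 entries and 12 libraries each. In each of them, 276 entries repeated another exactly and were dropped, leaving 40481 genes. The lowest value was -5.62 in all 24 libraries, which stands for 0 reads. Taking it as the log2 of a small prior (0.496 reads in a library of mean depth) turned every value within a tolerance of 0.05 reads into a whole multiple of 1 read per library (100% of the low values tested). From this, CPM values and the reads assigned per library were recovered: 16.97 to 24.2 M in the ileum and 26.4 to 32.3 M in the liver. No composition factor had been applied. Of the recovered read numbers, 69.0 to 72.8% were even in the ileum and 67.1 to 70.2% in the liver, against the 50% of independent reads, so both mates of most fragments had been counted, and the precision given by the reads is up to a factor of 2 lower in variance. The gene with the most reads took 4.09 to 5.85% of a liver library. It was Alb, but the predicted gene Gm26917 in Villin-Cre vehicle libraries (4.12 to 4.25%) and floxed GW3965 replicate 1 (5.54%). In the ileum it was Gm26917, whose share went with the groups. It took 10.4 to 11.6% and 6.56 to 7.905% in floxed mice (vehicle, GW3965) and 11.5 to 12.2% and 3.92 to 4.199% in Villin-Cre mice. In the same group order, ileal depth was 16.97 to 20.2, 17.7 to 22.9, 17.1 to 19.4 and 21.1 to 24.2 M reads. Genes encoded in mitochondria took 2.30 to 4.45% in the ileum and 1.93 to 3.10% in the liver.

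The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That design was written for read counts. Since log2 values were deposited, the test written for normalized values was used: limma 3.58.1 in R 4.3.3 on log2(CPM + 0.5), with 1 mean per group over the 12 libraries of a tissue, an empirical Bayes trend, and Benjamini-Hochberg adjustment with a threshold of 0.05. Contrasts were GW3965 against vehicle in each genotype, Villin-Cre against floxed in each treatment, and the interaction. Genes at 0.5 CPM or more in at least 3 libraries were tested (18656 in the ileum, 17520 in the liver), a filter set once the unit was known. The comparison of the GW3965 effect between tissues had been planned only for tables of read counts. That condition was not met, and the comparison was run all the same, over 16322 genes tested in both tissues, because both tables share their lowest value, as tables scaled together would; this was decided after the tables were seen and not tested further.

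Fixed gene lists, 46 in all, covered sterol, lipid and bile acid metabolism, drug metabolism, inflammation, matrix, stress responses and the cell types that ileum and liver can hold. Lists with at least 4 tested members (36 in the ileum, 34 in the liver) were tested with camera at the preset correlation of 0.01, without Abca1, adjusted over the lists of a tissue and contrast, and again with an estimated correlation and with fry. Named genes are Abca1, up to 8 genes each way with the largest log2 fold change among those past the threshold, with no overlap between the groups compared and a mean of at least 1 CPM in the higher group (predicted genes, pseudogenes and immunoglobulin or T cell receptor segments left out), up to 4 members of each described list with the smallest p, and LXR targets in the GW3965 contrasts. Some genes this rule takes are not reported here. For the interaction and the tissue difference no overlap rule was applied. Coordinates come from the GENCODE annotation of GRCm38, in which 19848 of 19854 tested genes (99.97%) were found.

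Alternatives were rescaling by the median of gene ratios, no filter, a fit of only the groups compared, an additive model, the replicate number as a block and leaving out each library. A pseudocount of 2, the deposited log2 values, voom on recovered reads, a list test on fold changes and averaging of close libraries (variance between libraries under 4 times the Poisson variance) were chosen after seeing the data. Steps were tested on simulated data with 200 changed genes of at least 5 CPM. Libraries had a coefficient of variation of 0.05 around the fitted group means and no spread between RNA sources, which can add false calls. For GW3965 in floxed ileum (18444 genes), 82.1% of 1.5-fold and 100% of 2-fold and 4-fold changes were recovered with 8 false calls. In floxed liver (17390 genes) it was 98.5%, 100% and 100% with 10. There, lists shifted by 0.5 log2 were called in 10 of 10 simulations per tissue. Of 350 unshifted lists, 0 (ileum) and 1 (liver) were called. Tables and plots used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.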

Results

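Gene expression was measured by RNA sequencing in the ileum and the liver of C57BL/6 mice that had lost 75% of the small bowel by resection. The floxed mice carried an Abca1 gene flanked by loxP sites and served as controls for the Villin-Cre mice, in which Cre recombinase driven by the Villin promoter of intestinal epithelium deletes that gene. ABCA1 is the transporter that loads cholesterol onto apolipoprotein A-I to form high-density lipoprotein. Mice of each genotype were given vehicle or GW3965, a synthetic agonist of the liver X receptors (LXR), which sense oxysterols and switch on genes of cholesterol export and fatty acid synthesis. GW3965 was given by mouth at 1 mg/kg/day, 2 times a week, during the last 5 of the 10 weeks after resection. The study asked whether this low oral dose acts on LXR in the intestine, and each of the 4 groups per tissue held 3 libraries, 24 in all. Depth was 16.97 to 24.2 M assigned reads per ileal and 26.4 to 32.3 M per liver library. Levels are given as CPM (reads of a gene over all assigned reads of the library, on a fixed scale), mean ± SD with n = 3, and fold changes as log2 ± SE on the log2(CPM + 0.5) scale, which understates the change of low genes. Values of genes with near-identical copies, such as the Cyp2c, Cyp2d, Cyp3a, Cyp4a, Ces2, Mup, defensin and interferon-induced GTPase families, and of overlapping or antisense genes are uncertain, since the counting could split or share their reads and its strand setting is not given in the sources used here.

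Apart from 1 library in each tissue, libraries of a group lay much closer to each other than to those of any other group. The variance between libraries, set against the Poisson variance of their reads, was 2.57 to 3.34 in 10 within-group pairs of the ileum and 2.59 to 3.10 in 10 pairs of the liver. Between groups it was 11.04 to 48.1 over 54 pairs of the ileum and 5.76 to 32.0 over 54 pairs of the liver. A library stood apart from its group in each tissue: replicate 3 of floxed mice given GW3965 in the ileum (10.4 and 10.5 against its group) and replicate 1 of the same treatment group in the liver (9.41 and 9.44). The close libraries differed by more than the factor of 2 that counting both mates of a fragment can give, so none was dropped as a library deposited more than once, but that factor does not tell separate animals from repeat libraries. The labels do not tie libraries to animals either, so the p-values measure the spread between libraries, which may be technical. Each count of genes is therefore also given with the close libraries averaged to 1, a setting chosen after the data were seen. That leaves 1 unit in each group but floxed GW3965, which has 2, so the spread rests on that 1 pair per tissue, the lone units are assumed to vary like it, and a low count does not show that an effect is absent. Within a tissue, the calls are also given in 1 simulation with no group effect and the difference between the library apart and the others of its group as spread. The list tests were not run with the close libraries averaged. Their estimated correlation also rests on the spread between libraries, so a list that held with it was not tested with the source as the unit.

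**Figure D1:**
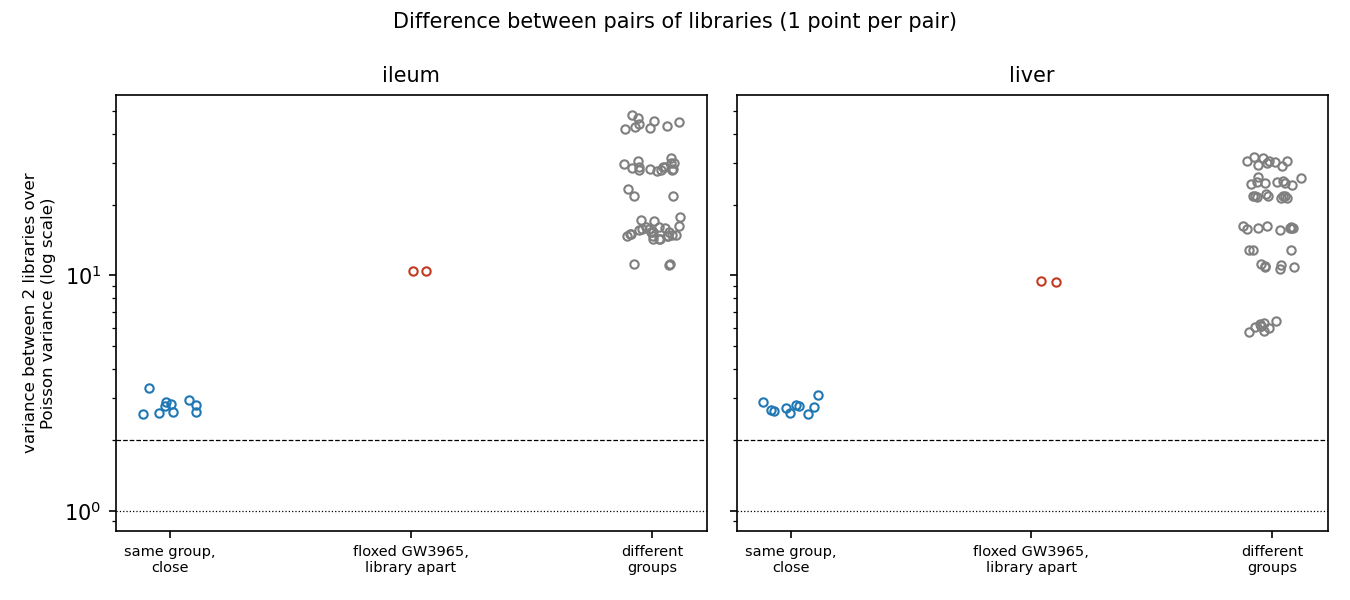
Variance between the reads of 2 libraries over the Poisson variance, on a log scale, with 1 point per pair of libraries in the ileum and the liver. Close pairs of a group lie at 2.57 to 3.34, pairs with the library apart at 9.41 to 10.5 and pairs from different groups at 5.76 to 48.1; the dotted line marks 1 and the dashed line 2.

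The deleted gene was lower in the Villin-Cre groups of both tissues. In the ileum, Abca1 stood at 57.2 ± 2.83 CPM in floxed mice given vehicle and at 28.3 ± 2.47 in Villin-Cre mice given vehicle. With GW3965 it stood at 372 ± 105 CPM in floxed mice, with 251.4 CPM in the library apart and 428 and 437.7 CPM in the others, and at 53.8 ± 0.158 in Villin-Cre mice. Villin drives Cre in epithelium and the values are sums over whole genes, so reads from other cells and from exons outside the deleted part are included. In the liver, outside the intended site of deletion, Abca1 stood at 335 ± 7.81 CPM in floxed and 225 ± 0.25 CPM in Villin-Cre mice given vehicle, and at 470.2 ± 8.03 and 379 ± 2.71 CPM with GW3965. Abca1 (ENSMUSG00000015243) lies on chromosome 4 at 53030787 to 53159895 on the minus strand (GRCm38). Read from the same annotation, the ileal LXR target Scd1 lies on chromosome 19 at 44394455 to 44407879 (minus strand) and the ileal regulator Gata4 on chromosome 14 at 63198922 to 63271692 (minus strand), all protein coding.

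**Figure D2:**
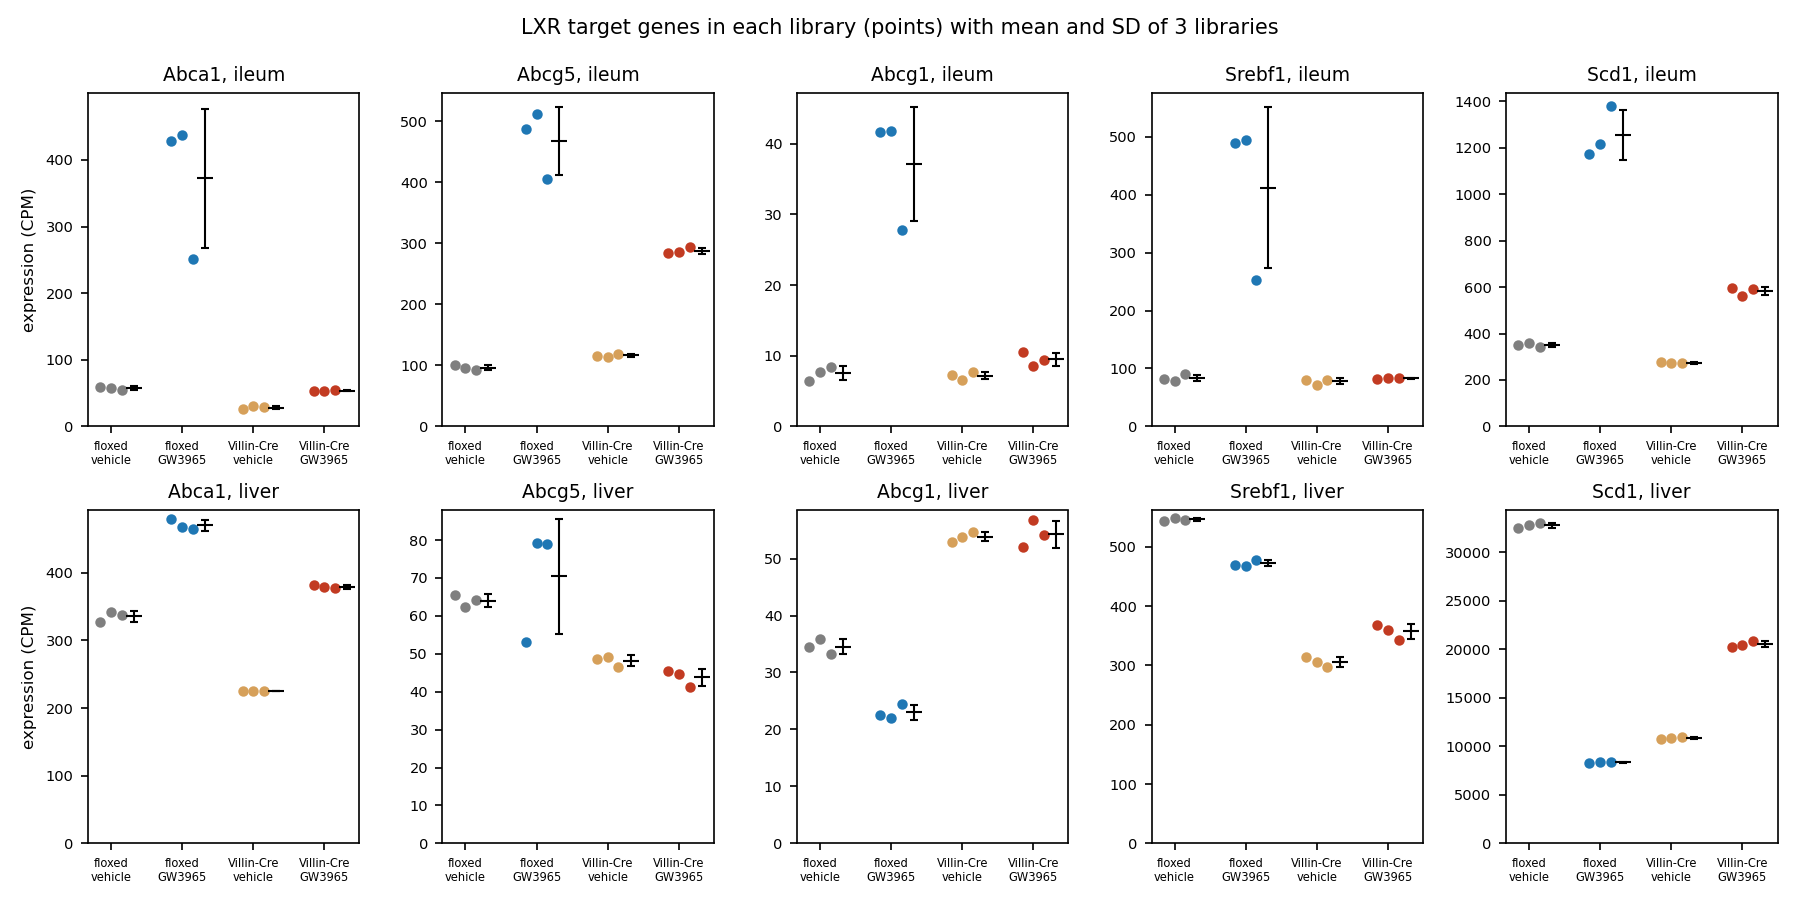
Expression (CPM) of Abca1 and the LXR target genes Abcg5, Abcg1, Srebf1 and Scd1 in each library (points) of the 4 groups in the ileum (top) and the liver (bottom), with the mean and SD of 3 libraries. In the ileum, Srebf1 stood at 412 ± 138 CPM in floxed mice given GW3965 and at 82.8 ± 0.637 CPM in Villin-Cre mice given GW3965; in the liver, Scd1 was highest in floxed mice given vehicle, at 32816 ± 264 CPM.

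The first comparison asked what GW3965 did in the ileum of floxed mice. Genes that LXR controls rose together: the sterol exporters Abcg5 and Abcg8, which return cholesterol to the gut lumen, went from 96.5 ± 3.49 to 468 ± 55.9 CPM and from 111 ± 4.84 to 473 ± 46.2 CPM (log2 fold changes 2.27 ± 0.07 and 2.08 ± 0.06). Abca1 rose by 2.65 ± 0.14 log2 (limma adjusted p = 4.2e-10). Absorptive enterocyte, lipid absorption and adipocyte genes were higher with GW3965, and macrophage and interferon genes were lower. In all, 2735 genes were higher and 3898 lower of 18656 tested, 564 and 485 of them by at least 2-fold.

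Of 19 LXR target genes tested besides Abca1, 13 rose, 1 fell and 5 did not pass (median log2 fold change 0.79, camera adjusted p = 1.1e-09). The ubiquitin ligase Mylip rose from 15.9 ± 0.76 to 73.1 ± 8.38 CPM, and the cholesterol exporter Abcg1 from 7.53 ± 0.964 to 37.1 ± 8.04 CPM. The lipogenic regulator Srebf1 rose from 83.5 ± 5.83 to 412 ± 138 CPM. The stearoyl-CoA desaturases Scd1 and Scd2 went from 350.1 to 1256 ± 108 CPM and from 274 to 1605 ± 664 CPM. Apoe, an apolipoprotein that LXR also controls, fell by 0.43 on the log2 scale. Among 21 fatty acid and triglyceride synthesis genes 9 rose and 3 fell (adjusted p = 0.0037, and adjusted p = 0.058 with an estimated correlation). Elovl6, a fatty acid elongase, stood lower at 40.1 ± 1.71 against 85.97 ± 6.31 CPM. Adjusted over the list alone, 13 LXR targets rose and 2 fell, and 11 synthesis genes rose and 4 fell.

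16 of 18 absorptive enterocyte markers rose and none fell (adjusted p = 4.9e-13), among them the brush border enzymes Alpi (180.3 ± 8.68 to 638 ± 9.897 CPM), Treh (1.52 ± 0.06 log2) and Mep1a (1.71 ± 0.10 log2). 12 of 18 intestinal lipid absorption genes rose and 2 fell (adjusted p = 2.1e-06): Npc1l1, the cholesterol importer of the brush border, went from 547 ± 13.04 to 1049.6 ± 22.2 CPM and the lipid regulator Creb3l3 from 75.4 ± 3.46 to 159 ± 12.7 CPM. In the ileal bile acid list 9 of 12 genes rose (adjusted p = 3.5e-05, and adjusted p = 0.11 with an estimated correlation), with log2 fold changes of 0.93 ± 0.05 for the bile acid importer Slc10a2 and 1.72 ± 0.10 for the exporter Abcc2. Gata4, which represses ileal genes in the proximal bowel, fell from 31.5 ± 2.81 to 3.54 ± 0.714 CPM. 9 of 19 xenobiotic response genes rose and 3 fell (adjusted p = 5.5e-04). The drug exporter Abcb1a stood at 509 ± 11.8 against 180.1 ± 8.08 CPM and the cytochrome P450 Cyp3a25 at 60.7 ± 24.5 against 4.59 ± 1.83 CPM. Genes with a large rise also included Cyp2d26 (3.64 ± 0.08 log2), the vitamin B12 receptor Cubn (3.09 ± 0.07 log2) and the steroid dehydrogenase Hsd3b3 (3.11 ± 0.11 log2). All 8 adipocyte markers rose (adjusted p = 8.0e-07), such as Plin1 (1.10 ± 0.12 log2) and Adipoq (1.06 ± 0.14 log2), which mark fat cells rather than epithelium. With p-values adjusted over the list alone, 13 lipid absorption genes rose and 2 fell, and the counts of the enterocyte, bile acid, xenobiotic and adipocyte lists did not change.

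Genes of dividing cells fell: 21 of 24 cell cycle genes (adjusted p = 1.1e-09, and adjusted p = 0.063 with an estimated correlation), with Mki67 down from 191 ± 15.3 to 84.2 ± 16.9 CPM and the topoisomerase Top2a from 115 ± 7.197 to 42.8 ± 6.85 CPM. 10 of 12 macrophage markers fell (adjusted p = 8.0e-07), including the complement gene C1qa (-1.20 ± 0.08 log2) and the receptor Csf1r (-1.15 ± 0.10 log2). 15 of 23 type I interferon response genes fell and 2 rose (adjusted p = 3.3e-05). The nucleic acid sensor Zbp1 fell from 100.2 ± 4.92 to 23.7 ± 8.05 CPM, and the interferon-induced GTPases Iigp1 and Tgtp1 changed by -2.79 ± 0.30 and -3.00 ± 0.26 log2. All 10 smooth muscle markers were lower (adjusted p = 4.5e-09, and adjusted p = 0.12 with an estimated correlation). Actg2 stood at 209.5 ± 60.5 against 698 ± 19.96 CPM and Tagln at 255 ± 52.6 against 580.2 ± 12.9 CPM. 22 of 27 fibrosis and matrix genes fell (adjusted p = 1.6e-08, and adjusted p = 0.14 with an estimated correlation), such as the fibronectin gene Fn1 (-1.36 ± 0.08 log2). Abca13, a relative of the deleted gene, fell from 12.7 ± 1.58 to 0.366 ± 0.268 CPM. When adjusted over the list alone, 23 cell cycle, 17 interferon and 23 matrix genes fell, and the macrophage and smooth muscle counts did not change.

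The list test placed 25 of 36 lists past the threshold, of which 8 kept their call with an estimated correlation: LXR targets, enterocytes, lipid absorption, xenobiotic response, adipocytes, macrophages, interferon response and the unfolded protein response. A further 7 lists rose and 3 fell, all with an adjusted p of at least 0.065 with an estimated correlation. Rescaling the libraries by the median of gene ratios moved the share of called genes that were higher from 41.2% to 53.5%. Simulated libraries with no group effect gave 2097 calls (458 by at least 2-fold). With the close libraries averaged, 150 genes were higher and 42 lower, among them 18 of the 36 genes named for this comparison.

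**Figure D3:**
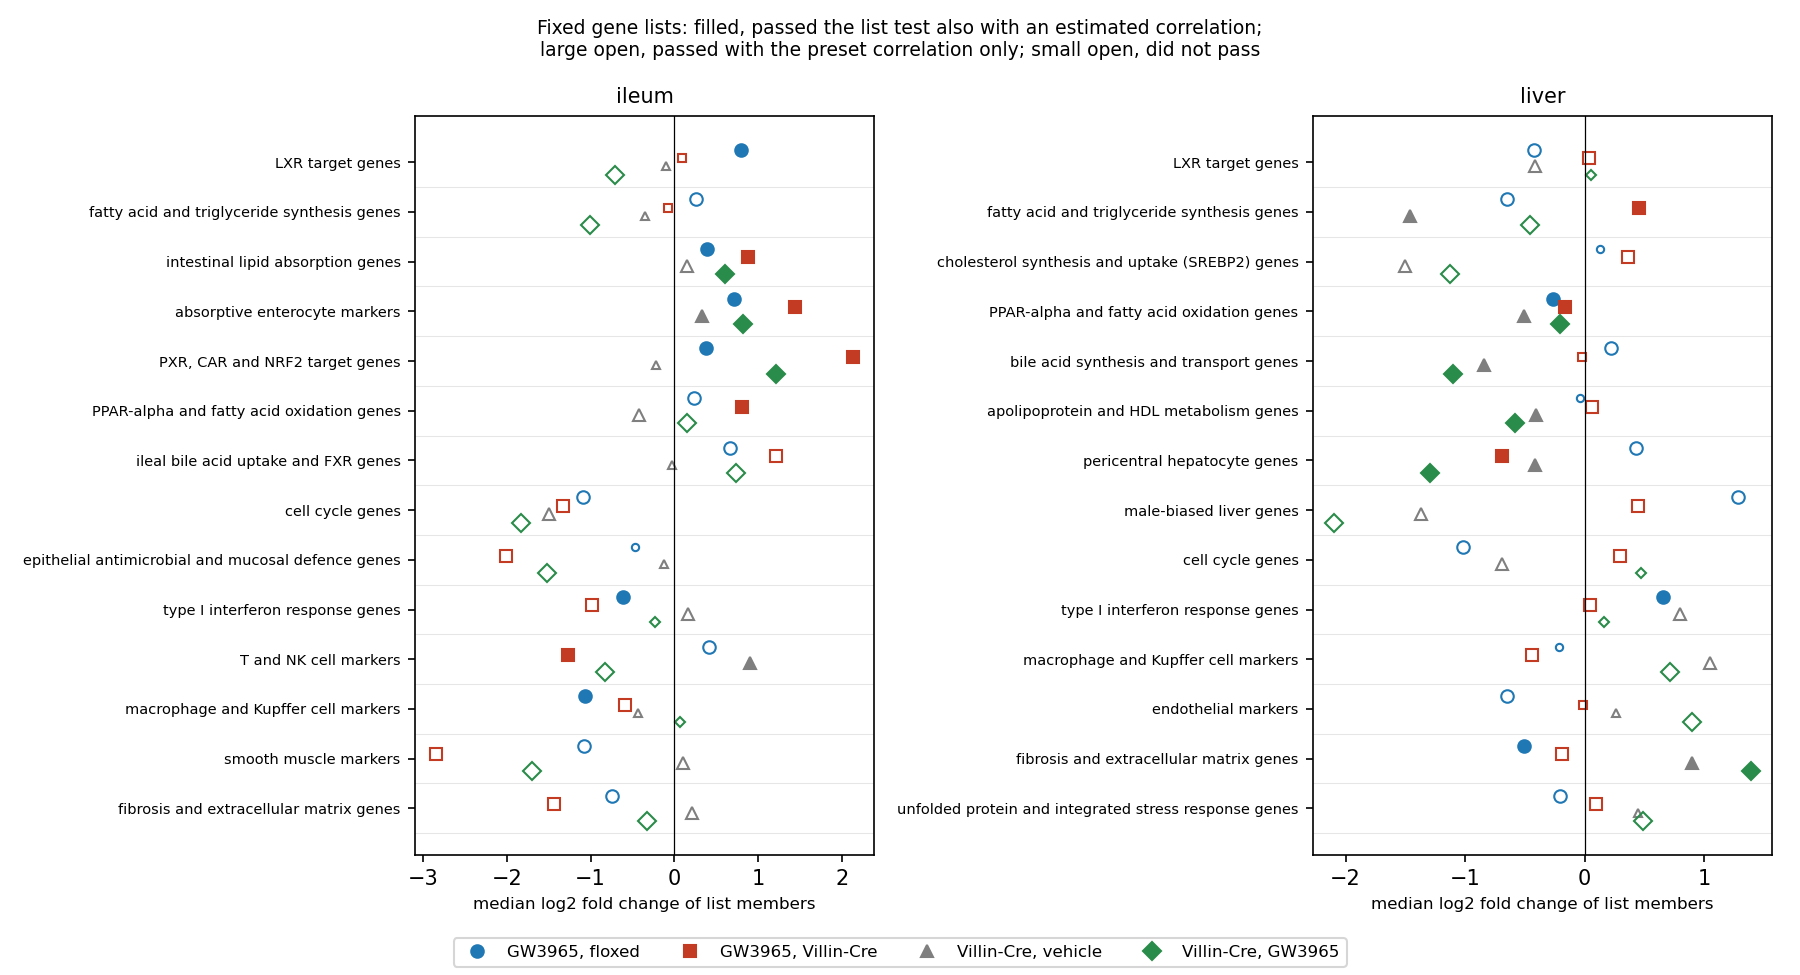
Median log2 fold change of the members of 14 fixed gene lists per tissue in the 4 comparisons of 2 groups. Filled symbols passed the list test also with an estimated correlation, large open symbols with the preset correlation only, and small open symbols did not pass; the LXR target list in the ileum lies at 0.79 with GW3965 in floxed mice and at 0.09 with GW3965 in Villin-Cre mice.

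In the ileum of Villin-Cre mice, 9799 genes passed with GW3965, and genes of drug metabolism were among its largest changes. The cytochrome P450 Cyp2c55 stood at 154 ± 3.11 CPM with GW3965 and at 0.109 ± 0.00715 CPM with vehicle, Cyp3a11 at 123 ± 4.31 against 2.44 ± 0.203 CPM and the glutathione transferase Gstm3 at 72.6 ± 5.55 against 0.838 ± 0.54 CPM. Enterocyte, lipid absorption and fatty acid oxidation genes were higher and T cell genes lower. In all, 4004 genes were higher and 5795 lower of 18656, 857 and 2270 of them by at least 2-fold.

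Among 19 LXR targets 9 rose, 7 fell and 3 did not pass, and as a list they missed the threshold (median 0.09, adjusted p = 0.14, and adjusted p = 0.27 with an estimated correlation). Abcg5 rose from 116 ± 2.44 to 288 ± 5.09 CPM, Abcg8 from 128 ± 1.83 to 306 ± 4.798 CPM, Scd1 from 273 ± 3.38 to 583 ± 17.2 CPM and Mylip from 19.2 ± 1.49 to 44.5 ± 1.69 CPM. Abca1 rose by 0.92 ± 0.14 log2. Srebf1 was at 82.8 ± 0.637 and 77.8 ± 5.03 CPM (log2 fold change 0.09 ± 0.17, adjusted p = 0.68) and Scd2 at 361 ± 10.2 and 349.6 ± 6.85 CPM (0.04 ± 0.21, adjusted p = 0.88) with GW3965 and vehicle, neither past the threshold. The fatty acid synthase gene Fasn fell from 307 ± 14.2 to 142 ± 8.34 CPM and the phospholipid transfer gene Pltp from 10.8 ± 1.11 to 4.095 ± 0.456 CPM. 17 of 19 xenobiotic response genes rose and 1 fell (adjusted p = 7.5e-13), with Abcb1a up 4.76 ± 0.05 log2 to 2840.4 ± 19.9 CPM and the carboxylesterase Ces2a up 4.63 ± 0.14 log2. Adjusted over the list alone, 17 xenobiotic response genes rose and 2 fell, and the LXR target counts did not change.

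All 18 enterocyte markers rose (adjusted p = 2.9e-14): the brush border lactase Lct went from 0.694 ± 0.478 to 61.1 ± 1.96 CPM and Alpi from 346 ± 17.3 to 1524 ± 9.702 CPM. 17 of 18 lipid absorption genes rose (adjusted p = 1.1e-11), with Fabp2, the fatty acid carrier of enterocytes, up 2.30 ± 0.09 log2, Creb3l3 up 2.29 ± 0.06 log2 and Npc1l1 up 0.96 ± 0.04 log2. 22 of 23 fatty acid oxidation genes rose and 1 fell (adjusted p = 7.5e-12). The thiolase Acaa1b went from 4.23 ± 0.356 to 81.97 ± 7.36 CPM and Cpt1a, which admits fatty acids to mitochondria, from 87.7 ± 1.91 to 173 ± 2.72 CPM. Bile acid genes rose in 11 of 12 cases (adjusted p = 2.4e-06, and adjusted p = 0.1 with an estimated correlation). The binding protein Fabp6 stood at 5163 ± 107 against 1220.2 ± 70.9 CPM. With p-values adjusted over the list alone, none of these counts changed.

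All 10 smooth muscle markers fell (median -2.84, adjusted p = 7.0e-11, and adjusted p = 0.12 with an estimated correlation): Acta2 went from 819.8 ± 22.96 to 139 ± 2.96 CPM and Tagln from 586 ± 18.9 to 73.3 ± 2.64 CPM. 24 of 27 matrix genes fell (adjusted p = 1.1e-11, and adjusted p = 0.12 with an estimated correlation), such as Fn1 (-2.14 ± 0.08 log2) and the proteoglycan Lum (-3.06 ± 0.17 log2). 12 of 15 antimicrobial genes fell (adjusted p = 2.1e-05, and adjusted p = 0.23 with an estimated correlation), among them the bactericidal lectins Reg3g (1396 ± 21.00 to 153 ± 0.407 CPM) and Reg3b (3211 ± 26.9 to 528 ± 19.3 CPM), and the serum amyloid gene Saa1 stood at 2.29 ± 0.331 against 155 ± 6.89 CPM. 13 of 14 T and NK cell markers fell (adjusted p = 2.1e-05), with the granzymes Gzmb and Gzma lower (-2.69 ± 0.16 and -1.70 ± 0.11 log2). 20 of 24 cell cycle genes fell (adjusted p = 3.0e-06, and adjusted p = 0.14 with an estimated correlation), Mki67 at -1.82 ± 0.11 and Top2a at -1.99 ± 0.10 log2. 19 of 23 interferon response genes fell (adjusted p = 3.4e-04, and adjusted p = 0.054 with an estimated correlation), Zbp1 from 83.6 ± 1.74 to 6.16 ± 0.929 CPM. The counts adjusted over the list alone were the same for these lists.

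Of 17 lists called, the xenobiotic, enterocyte, lipid absorption, fatty acid oxidation and T and NK cell lists held with an estimated correlation, and 4 lists that fell and 1 that rose are not detailed here (adjusted p of at least 0.054 with an estimated correlation). Rescaling by the median of gene ratios shifted the median of all genes by 0.11 log2, with 5043 genes then higher and 4996 lower. After averaging the close libraries, 580 genes were higher and 881 lower, among them 28 of the 32 genes named here as changed. With no group effect, simulated libraries gave 2992 calls (609 by at least 2-fold).

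The response to GW3965 differed between genotypes in the ileum. The difference, taken as the change in Villin-Cre mice minus that in floxed mice, was below 0 for LXR targets and T cell and neuronal markers, and above 0 for drug metabolism, fatty acid oxidation and enterocyte genes. Abca1 itself had a difference of -1.73 ± 0.20 log2 (adjusted p = 5.9e-06). The test found 2729 genes with a difference above 0 and 3425 below it, 2371 of them of at least 2-fold, against 2398 and 1017 in simulated libraries with no group effect.

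14 of 19 LXR targets had a difference below 0 and 2 above it (median -0.91, adjusted p = 7.5e-06), with -2.14 ± 0.24 log2 for Srebf1, -1.83 ± 0.21 for Abcg1, -0.96 ± 0.10 for Abcg5 and -0.75 ± 0.08 for Scd1. The fatty acid and triglyceride synthesis genes followed, 12 of 21 below 0 and 4 above (adjusted p = 0.0072, and adjusted p = 0.07 with an estimated correlation). For the xenobiotic list 15 of 19 genes were above 0 (adjusted p = 2.2e-13), led by Cyp2c55 at 5.33 ± 0.30 log2 and Abcb1a at 3.26 ± 0.07 log2. Fatty acid oxidation genes were above 0 in 15 of 23 cases (adjusted p = 1.6e-08; Cpt1a 0.85 ± 0.07 log2) and enterocyte markers in 13 of 18 (adjusted p = 7.5e-06; Lct 5.27 ± 0.39 and Fabp2 1.85 ± 0.13 log2). 13 of 14 T and NK cell markers were below 0 (adjusted p = 2.3e-08). Gzmb lay at -2.98 ± 0.23 and Cd8a at -2.20 ± 0.22 log2. All 10 smooth muscle markers were below 0 (adjusted p = 3.0e-11, and adjusted p = 0.12 with an estimated correlation; Acta2 -1.84 ± 0.11 log2), as were 10 of 12 enteric neuron markers (adjusted p = 4.0e-05; Nos1 -2.10 ± 0.21 log2). 12 of 17 unfolded protein response genes were above 0 (adjusted p = 1.7e-05), such as the chaperone Hspa5 at 0.82 ± 0.07 log2. 9 of 15 antimicrobial genes were below 0 (adjusted p = 1.2e-05, and adjusted p = 0.24 with an estimated correlation; Reg3g -2.06 ± 0.13 log2). Gata4 had one of the larger differences, 4.19 ± 0.20 log2, since it fell with GW3965 in floxed mice and stood at 4.83 ± 0.386 CPM with vehicle and 11.6 ± 0.762 CPM with GW3965 in Villin-Cre mice.

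When adjusted over the list alone, the counts above and below 0 were 3 and 14 for LXR targets, 4 and 13 for lipid synthesis, 17 and 0 for xenobiotic response, 16 and 1 for fatty acid oxidation, 13 and 2 for enterocytes, 12 and 2 for the unfolded protein response and 0 and 10 for antimicrobial genes, with the others as given. Of 23 lists called, 8 held with an estimated correlation: LXR targets, xenobiotic response, fatty acid oxidation, enterocytes, T and NK cells, enteric neurons, the unfolded protein response and stellate cells and fibroblasts. Averaging the close libraries left 14 genes past the threshold, Abcb1a among them (adjusted p = 0.049) and none of the other 16 genes named here.

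Without GW3965, the ileum of Villin-Cre mice had higher T cell and enterocyte markers than that of floxed mice. Signs of RNA composition moved with genotype: Lars2 ran from 839 to 1085 CPM in floxed and from 1499.7 to 2823 CPM in Villin-Cre libraries, and genes encoded in mitochondria took 3.62 to 4.45% and 2.30 to 2.796% of reads. Olfm4, a crypt stem cell marker, stood at 10.8 ± 0.283 CPM against 56.5 ± 1.97 CPM in floxed mice, and the granzyme Gzma at 49.1 ± 0.798 against 12.6 ± 1.07 CPM. Abca1 was lower (-1.01 ± 0.14 log2, adjusted p = 3.5e-05). In all, 1792 genes were higher and 5735 lower, 328 and 755 by at least 2-fold.

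All 24 cell cycle genes were lower (adjusted p = 6.4e-12, and adjusted p = 0.067 with an estimated correlation). Top2a stood at 30.1 ± 1.01 against 115 ± 7.197 CPM and Mki67 at 53.3 ± 2.14 against 191 ± 15.3 CPM. 8 of 12 stem and crypt genes fell (adjusted p = 0.0098, and adjusted p = 0.2 with an estimated correlation), the crypt receptor Ephb2 at -1.21 ± 0.13 log2. 8 of 10 Paneth cell genes passed as lower, such as Mmp7 (-2.20 ± 0.43 log2) and the defensin Defa24 (-1.33 ± 0.35 log2), though the list did not (adjusted p = 0.054, and adjusted p = 0.59 with an estimated correlation). 10 of 14 T and NK cell markers rose (adjusted p = 1.9e-08), including Cd8a (5.800 ± 1.01 to 18.5 ± 0.937 CPM) and Itgae (20.9 ± 1.56 to 47.2 ± 0.83 CPM), an integrin of intraepithelial lymphocytes. 6 of 9 tuft cell markers rose and 1 fell (adjusted p = 5.2e-05, and adjusted p = 0.067 with an estimated correlation). The taste channel Trpm5 stood at 17.8 ± 2.56 against 4.84 ± 0.971 CPM. Enterocyte markers rose in 10 and fell in 3 of 18 cases (adjusted p = 2.4e-05), Alpi by 0.94 ± 0.05 and Treh by 0.98 ± 0.06 log2, while the fructose importer Slc2a5 stood at 34.5 ± 3.71 against 64.4 ± 2.24 CPM. 15 of 25 cholesterol synthesis and uptake genes rose and 3 fell (adjusted p = 1.3e-06, and adjusted p = 0.32 with an estimated correlation), with Hmgcs1, an early enzyme of the pathway, up 0.84 ± 0.08 log2 and the squalene synthase Fdft1 up 0.73 ± 0.10 log2. 13 of 23 fatty acid oxidation genes fell and 1 rose (adjusted p = 0.0051, and adjusted p = 0.2 with an estimated correlation), Cpt1a from 184 ± 3.54 to 87.7 ± 1.91 CPM and Acadl at -1.22 ± 0.09 log2.

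Among 19 LXR targets 4 rose and 5 fell (adjusted p = 0.72); the test statistic pointed up while the median and mean were -0.10 and -0.07, and after rescaling by the median of gene ratios the median was 0.15. Scd1 and Fasn were lower (-0.36 ± 0.06 and -0.86 ± 0.09 log2), Scd1 no longer past the threshold after that rescaling. Gata4 stood at 4.83 ± 0.386 against 31.5 ± 2.81 CPM. Some large differences were in genes of no shared function. Zfp652 (chromosome 11, 95712673 to 95835115, plus strand) stood at 2712 ± 256 against 99.8 ± 5.25 CPM, the autophagy gene Atg3 at 374 ± 47.8 against 31.9 ± 0.568 CPM and Snx33 at 122 ± 3.77 against 12.2 ± 0.891 CPM. Ffar2, a receptor for short-chain fatty acids (chromosome 7, 30818348 to 30823775, minus strand), stood at 20.3 ± 0.245 against 1453 ± 104 CPM, Bbof1 at 4.66 ± 0.0266 against 405 ± 52.03 CPM and Crmp1 at 3.65 ± 0.292 against 172 ± 12.4 CPM. Under voom, which weights each value by its expected precision, these 3 genes did not pass (adjusted p of 0.116, 0.24 and 0.231). Their fold changes were -6.12 ± 1.14, -6.29 ± 1.14 and -5.38 ± 1.04 log2 in the trend fit and -6.16 ± 2.95, -6.43 ± 4.11 and -5.545 ± 3.478 log2 under voom, so the call ended with the larger error. The metallothionein Mt2 (-4.82 ± 0.13 log2) and the phospholipase Plb1 (-4.56 ± 0.46 log2) were also lower.

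Adjusted over the list alone, 4 LXR targets rose and 6 fell, and the other counts did not change. Of 17 lists called, the T and NK cell and enterocyte lists held with an estimated correlation; 7 more rose and 3 more fell (adjusted p of at least 0.067 with an estimated correlation). Rescaling by the median of gene ratios shifted the median of all genes by 0.24 log2 and the share of called genes that were higher from 23.8% to 58.1%. When the close libraries were averaged, 16 genes were higher and 5 lower, 4 of the 29 named here among them (Zfp652, Atg3, Snx33 and Mt2). The simulation with no group effect called 3119 genes (652 by at least 2-fold).

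Under GW3965, the ileum of Villin-Cre mice had higher drug metabolism and enterocyte genes than that of floxed mice. LXR target and lipid synthesis genes were lower (adjusted p = 0.052 and 0.12 with an estimated correlation). Abca1 differed by -2.74 ± 0.14 log2, Srebf1 stood at 82.8 ± 0.637 against 412 ± 138 CPM and Fasn at 142 ± 8.34 against 626 ± 104 CPM. In all, 2529 genes were higher and 7153 lower, 438 and 2291 by at least 2-fold.

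14 of 19 LXR targets were lower and 2 higher (median -0.70, adjusted p = 4.4e-04, and adjusted p = 0.052 with an estimated correlation): Abcg1 stood at 9.49 ± 0.972 against 37.1 ± 8.04 CPM, Abcg5 at 288 ± 5.09 against 468 ± 55.9 CPM and Scd1 at 583 ± 17.2 against 1256 ± 108 CPM. 13 of 21 lipid synthesis genes were lower and 3 higher (adjusted p = 0.0098, and adjusted p = 0.12 with an estimated correlation). The carboxylase Acaca lay at -1.32 ± 0.07 and the desaturase Fads2 at -2.10 ± 0.11 log2. 15 of 19 xenobiotic response genes were higher and 1 lower (adjusted p = 4.7e-15): Cyp2c55 by 5.11 ± 0.21, Ces2a by 3.69 ± 0.14 and Abcb1a by 2.48 ± 0.05 log2. 15 of 18 enterocyte markers were higher and none lower (adjusted p = 4.7e-15), Alpi by 1.26 ± 0.05 and Lct by 4.01 ± 0.28 log2. 13 of 18 lipid absorption genes were higher and 3 lower (adjusted p = 9.9e-09). Fabp2 stood at 3329 ± 17.9 against 874 ± 167 CPM and Npc1l1 at 1754 ± 39.4 against 1049.6 ± 22.2 CPM.

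12 of 15 antimicrobial genes were lower (adjusted p = 2.9e-04, and adjusted p = 0.32 with an estimated correlation). Reg3g stood at 153 ± 0.407 against 2034 ± 377 CPM, Reg3b at 528 ± 19.3 against 4595 ± 862 CPM and Saa1 at 2.29 ± 0.331 against 229 ± 124 CPM. All 10 Paneth cell genes were lower (adjusted p = 0.001, and adjusted p = 0.42 with an estimated correlation; Defa24 -2.52 ± 0.35 log2). So were 9 of 10 goblet cell genes (adjusted p = 5.7e-04, and adjusted p = 0.13 with an estimated correlation), such as Spink4 (-2.29 ± 0.08 log2) and the mucin chaperone Agr2 (-0.89 ± 0.06 log2). 9 of 12 stem and crypt genes were lower (adjusted p = 9.5e-04, and adjusted p = 0.13 with an estimated correlation), Olfm4 at 1.79 ± 0.503 against 20.5 ± 5.45 CPM and Ephb2 at 6.43 ± 1.601 against 29.3 ± 1.92 CPM. 22 of 24 cell cycle genes were lower (adjusted p = 9.0e-09, and adjusted p = 0.12 with an estimated correlation), Top2a at -2.48 ± 0.10 and Mki67 at -2.45 ± 0.11 log2. All 10 smooth muscle markers were lower (adjusted p = 1.3e-07, and adjusted p = 0.2 with an estimated correlation), Acta2 at -1.71 ± 0.07 and Tagln at -1.77 ± 0.09 log2. With p-values adjusted over the list alone, 2 xenobiotic genes were lower, 4 lipid synthesis genes higher, 23 cell cycle genes lower and 10 stem and crypt genes lower, with the other counts as given.

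Of 22 lists called, the xenobiotic, enterocyte and lipid absorption lists held with an estimated correlation, and 7 more rose and 4 more fell (adjusted p of at least 0.11 with an estimated correlation). The median of gene ratios shifted the median of all genes by 0.26 log2 and the share of called genes that were higher from 26.1% to 52.2%. With the close libraries averaged, 304 genes were higher and 927 lower, including 24 of the 27 named here. Simulated libraries with no group effect gave 2110 calls (430 by at least 2-fold).

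In the liver of floxed mice the question was whether the oral dose reached LXR there. Abca1 rose from 335 ± 7.81 to 470.2 ± 8.03 CPM (0.49 ± 0.04 log2, adjusted p = 5.9e-07; adjusted p = 0.69 with the close libraries averaged), whereas most other LXR targets that passed fell. Fatty acid oxidation and matrix genes were lower with GW3965 and interferon response genes higher. The desaturase gene Scd1 fell from 32816 ± 264 to 8365 ± 43.2 CPM and Scd2 from 497 ± 6.21 to 81.4 ± 2.49 CPM. In all, 1814 genes were higher and 3451 lower of 17520, 161 and 278 by at least 2-fold.

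10 of 20 LXR targets fell and 2 rose (median -0.42, adjusted p = 0.0016, and adjusted p = 0.23 with an estimated correlation). Abcg1 stood at 23.02 ± 1.32 against 34.6 ± 1.28 CPM and the lipoprotein lipase gene Lpl at 54.1 ± 9.17 against 139 ± 2.41 CPM. 12 of 21 lipid synthesis genes fell and 2 rose (adjusted p = 9.7e-05, and adjusted p = 0.19 with an estimated correlation), the elongase Elovl5 at -0.76 ± 0.04 and Fads2 at -0.87 ± 0.05 log2. 18 of 24 PPAR-alpha and fatty acid oxidation genes fell and none rose (adjusted p = 1.5e-07): the lipid droplet gene Plin2 went from 926 ± 27.2 to 484 ± 49.1 CPM, the peroxisomal enzyme Ehhadh from 929 ± 21.5 to 431 ± 81.7 CPM and the fasting hormone Fgf21 from 86.1 ± 6.61 to 18.5 ± 8.74 CPM. 12 of 20 bile acid genes rose and 2 fell (adjusted p = 6.6e-05, and adjusted p = 0.19 with an estimated correlation). Cyp7b1 stood at 46.1 ± 13.8 against 18.1 ± 0.792 CPM and the repressor Nr0b2 at 38.6 ± 4.22 against 15.7 ± 1.05 CPM. 5 of 11 pericentral hepatocyte genes rose and 1 fell (adjusted p = 0.002, and adjusted p = 0.055 with an estimated correlation), Oat by 0.93 ± 0.11 and Cyp2e1 by 0.86 ± 0.05 log2. 6 of 9 male-biased genes rose (adjusted p = 2.2e-04, and adjusted p = 0.33 with an estimated correlation), such as Cyp4a12a (1.48 ± 0.21 log2).

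16 of 23 interferon response genes rose and 1 fell (adjusted p = 2.3e-09). Ifit1 stood at 11.3 ± 0.634 against 3.87 ± 0.164 CPM. 21 of 27 matrix genes fell (adjusted p = 6.8e-11), Spp1 at -1.23 ± 0.09, the collagen Col4a1 at -0.73 ± 0.05 and Sparc at -0.85 ± 0.05 log2. 15 of 24 cell cycle genes fell (adjusted p = 2.7e-06, and adjusted p = 0.23 with an estimated correlation). Mki67 stood at 19.5 ± 2.74 against 63.5 ± 1.68 CPM and Cdc20 at 6.32 ± 0.161 against 26.1 ± 0.869 CPM. 11 of 12 endothelial markers fell (adjusted p = 5.4e-06, and adjusted p = 0.19 with an estimated correlation), the VEGF receptor Kdr at -1.11 ± 0.10 log2. Large falls were seen in Slc7a11, a cystine importer (-3.42 ± 0.12 log2), and Psat1 of serine synthesis (-2.90 ± 0.09 log2), and ribosomal RNAs, of the kind that the library protocol removes, were among the largest rises (mt-Rnr2 2.72 ± 0.38, mt-Rnr1 2.64 ± 0.39 and n-R5-8s1 2.41 ± 0.34 log2), with Mir6236 (2.59 ± 0.30 log2) and Lars2 (2.48 ± 0.33 log2). Lars2 ran from 252 to 434 CPM in libraries of floxed mice given vehicle, 1271 to 2403 with GW3965, and 342 to 782 and 908 to 2049 CPM in Villin-Cre mice in the same order. When adjusted over the list alone, 5 LXR targets rose and 14 fell, 14 lipid synthesis and 20 fatty acid oxidation genes fell, 14 bile acid genes rose and 2 pericentral genes fell, with the other counts as given.

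Of 17 lists called, the fatty acid oxidation, matrix and interferon lists held with an estimated correlation; 2 more rose and 5 more fell (adjusted p of at least 0.055 with an estimated correlation). With only these 2 groups in the fit 3458 genes were called, and 2673 with the treatment effect taken over both genotypes. After averaging the close libraries, 2 genes were higher and 3 lower: mt-Rnr1 and mt-Rnr2, and Scd2, Slc7a11 and Psat1. After rescaling by the median of gene ratios the share of called genes that were higher went from 34.5% to 46.4%. With no group effect, simulated libraries gave 2375 calls (339 by at least 2-fold).

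With GW3965, 2081 genes passed in the liver of Villin-Cre mice, against 5265 in floxed mice and 3437 in simulated libraries with no group effect (111 against 482 simulated by at least 2-fold). With only the 2 groups compared in each fit the order turned, 4818 against 3458. Abca1 rose from 225 ± 0.25 to 379 ± 2.71 CPM (0.75 ± 0.04 log2) and lipid synthesis genes rose, Scd1 from 10877 ± 70.6 to 20539 ± 282 CPM and Fads2 from 859.6 ± 5.304 to 1345 ± 12.9 CPM. Both turned negative where the treatment effect was taken over both genotypes together, at -0.53 and -0.11 log2. Pericentral, cholangiocyte and stellate genes were lower. In all, 499 genes were higher and 1582 lower, 32 and 79 by at least 2-fold.

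7 of 21 lipid synthesis genes rose and none fell (median 0.46, adjusted p = 3.8e-15), and 1 of 25 cholesterol synthesis and uptake genes passed, as higher (list adjusted p = 4.9e-07, and adjusted p = 0.42 with an estimated correlation). Of 20 LXR targets 3 rose and 1 fell (median 0.04, adjusted p = 0.0037, and adjusted p = 0.26 with an estimated correlation). Srebf1 stood at 357 ± 12.8 against 306 ± 8.77 CPM. 6 of 11 pericentral genes fell (adjusted p = 7.8e-08): the glutamine synthetase Glul went from 503 ± 6.19 to 257 ± 6.07 CPM, the glutamate importer Slc1a2 from 105 ± 4.98 to 43.02 ± 1.66 CPM and Cyp1a2 from 277 ± 1.94 to 129.7 ± 4.91 CPM. 2 of 11 periportal genes rose and 1 fell (adjusted p = 3.3e-04), the glutaminase Gls2 by 0.68 ± 0.07 log2. 10 of 24 fatty acid oxidation genes fell (adjusted p = 3.8e-06), Cyp4a10 at -0.63 ± 0.04 and Acaa1b at -0.58 ± 0.10 log2. 9 of 12 stellate cell and fibroblast markers fell (adjusted p = 7.8e-08). Dcn stood at 166 ± 4.85 against 281 ± 2.68 CPM and the growth factor Hgf at 55.3 ± 1.95 against 89.5 ± 1.06 CPM. 7 of 10 bile duct markers fell (adjusted p = 3.3e-04), Epcam at -1.22 ± 0.19 and Krt7 at -1.29 ± 0.24 log2. 9 of 16 macrophage and Kupffer cell markers fell (adjusted p = 7.8e-08, and adjusted p = 0.22 with an estimated correlation), the scavenger receptor Cd163 at -1.19 ± 0.11 and C1qc at -0.63 ± 0.09 log2. The protease Mmp7 (-2.19 ± 0.15 log2) and Spp1 (-1.02 ± 0.09 log2) were lower, and the major urinary protein gene Mup3 higher at 109 ± 5.59 against 27.4 ± 1.63 CPM.

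Adjusted over the list alone, 12 lipid synthesis and 4 periportal genes rose, and 8 pericentral, 14 fatty acid oxidation, 10 stellate, 9 bile duct and 13 macrophage genes fell, with the other counts as given. Of 23 lists called, the lipid synthesis, pericentral, periportal, fatty acid oxidation, stellate and bile duct lists held with an estimated correlation; 8 more rose and 6 more fell (adjusted p of at least 0.051 with an estimated correlation). Leaving out any of the 6 libraries compared brought the 2081 called genes to between 1084 and 1286. When the close libraries were averaged, which sets 1 unit against 1 here, limma called 0 genes, with 209 at an unadjusted p under 0.05, and none of the 19 named here passed. The share of called genes that were higher was 23.98% and, after rescaling by the median of gene ratios, 59.8%.

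In the liver the test also called differences between genotypes in the response to GW3965, with pericentral genes below 0 in the difference (Villin-Cre minus floxed). Scd1 fell in floxed mice and rose in Villin-Cre mice, a difference of 2.89 ± 0.10 log2 (adjusted p = 8.5e-10), and Scd2 differed by 2.99 ± 0.06 log2. Abca1 had a difference of 0.27 ± 0.05 log2. The test found 1780 genes above 0 and 1699 below it, 649 of them of at least 2-fold. Simulated libraries with no group effect gave 2752, of which 884, more than in the data, were of at least 2-fold.

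13 of 21 lipid synthesis genes were above 0 and 2 below (adjusted p = 1.5e-10, and adjusted p = 0.072 with an estimated correlation; Fads2 1.52 ± 0.07 log2). So were 11 of 20 LXR targets, with 2 below (adjusted p = 3.4e-05, and adjusted p = 0.14 with an estimated correlation; Lpl 1.02 ± 0.13 and Abcg1 0.59 ± 0.08 log2). 14 of 24 cell cycle genes were above 0 (adjusted p = 1.5e-10, and adjusted p = 0.14 with an estimated correlation), Cdc20 at 2.43 ± 0.14 and Mki67 at 2.12 ± 0.12 log2. Also above 0 were 14 of 27 matrix genes (adjusted p = 5.0e-06, and adjusted p = 0.086 with an estimated correlation; Sparc 0.91 ± 0.07 log2) and 7 of 12 endothelial markers (adjusted p = 3.6e-06, and adjusted p = 0.17 with an estimated correlation; Kdr 1.15 ± 0.14 log2). 7 of 11 pericentral genes were below 0 (adjusted p = 3.6e-06). Slc1a2 lay at -2.19 ± 0.07, Glul at -1.40 ± 0.06 and Cyp2e1 at -1.34 ± 0.07 log2. 14 of 23 interferon response genes were below 0 and 2 above (adjusted p = 5.5e-05, and adjusted p = 0.086 with an estimated correlation; Ifit1 -1.59 ± 0.14 log2). The bile acid repressor Nr0b2 had a difference of -1.95 ± 0.12 log2. With p-values adjusted over the list alone, 14 lipid synthesis, 15 cell cycle, 15 matrix and 10 endothelial genes were above 0 and 3 LXR targets below it, with the other counts as given.

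Of 12 lists called, the pericentral list alone held with an estimated correlation. Without replicate 1 of floxed mice given GW3965, the library apart, 5718 genes passed in place of 3479 and 19 lists in place of 12. With the close libraries averaged, limma called 0 genes, with 505 at an unadjusted p under 0.05.

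Villin-Cre and floxed liver differed broadly with vehicle, but close libraries may share a source, not separable from genotype. Lipid synthesis, bile acid and lipoprotein genes were lower in Villin-Cre mice and matrix genes higher. Cyp8b1 and Cyp7a1, enzymes of bile acid synthesis, stood at 14.7 ± 0.602 against 356 ± 4.64 CPM and at 18.03 ± 0.738 against 249 ± 13.2 CPM. Abca1 was lower (-0.57 ± 0.04 log2, adjusted p = 1.7e-08). In all, 7894 genes were higher and 2057 lower, 1219 and 520 by at least 2-fold.

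19 of 21 lipid synthesis genes were lower and none higher (median -1.46, adjusted p = 5.4e-19). Scd1 stood at 10877 ± 70.6 against 32816 ± 264 CPM, Elovl5 at 587 ± 5.96 against 1843 ± 44.03 CPM and Fads2 at 859.6 ± 5.304 against 1930.1 ± 15.5 CPM. 24 of 25 cholesterol synthesis and uptake genes were lower (adjusted p = 3.0e-14, and adjusted p = 0.21 with an estimated correlation), the sterol isomerase Ebp at -1.21 ± 0.14 and the sterol transfer protein Stard4 at -0.94 ± 0.09 log2. 14 of 20 bile acid genes were lower and 4 higher (adjusted p = 5.3e-11), among them the importer Slc10a1 (-2.14 ± 0.05 log2). 13 of 19 apolipoprotein and HDL genes were lower (adjusted p = 5.3e-11). Apoa2 stood at 1081 ± 19.5 against 2401 ± 10.7 CPM and the hepatic lipase Lipc at 33.1 ± 0.736 against 77.8 ± 1.43 CPM. 12 of 20 LXR targets were lower and 5 higher (adjusted p = 6.8e-07, and adjusted p = 0.073 with an estimated correlation; Srebf1 -0.83 ± 0.04 log2). 19 of 24 fatty acid oxidation genes were lower and 5 higher (adjusted p = 2.0e-09): Cyp4a10 at -1.30 ± 0.04 log2, while the lipid droplet gene Plin2 was higher at 1947 ± 14.9 against 926 ± 27.2 CPM. 9 of 11 hepatocyte genes were lower (adjusted p = 4.1e-08, and adjusted p = 0.074 with an estimated correlation; Ttr -1.14 ± 0.10 log2). So were 8 of 11 pericentral genes, with 3 higher (adjusted p = 3.4e-05; Glul -0.82 ± 0.04 and Cyp2e1 -1.13 ± 0.05 log2). 7 of 9 male-biased genes were lower (adjusted p = 7.8e-07, and adjusted p = 0.2 with an estimated correlation). Cyp4a12a stood at 1.58 ± 0.319 against 17.7 ± 0.628 CPM and the elongase Elovl3 at 0.192 ± 0.0425 against 8.32 ± 0.81 CPM, with fold changes of -3.67 ± 0.45 log2 for Elovl3 in the trend fit and -5.33 ± 2.78 log2 under voom (adjusted p = 0.117), where its larger error ended the call. Car3, a carbonic anhydrase abundant in male liver, stood at 35.3 ± 0.785 against 638 ± 9.55 CPM.

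25 of 27 matrix genes were higher and 1 lower (adjusted p = 8.5e-08). The collagen Col1a2 stood at 153 ± 5.15 against 73.7 ± 2.19 CPM, and Thbs1 and the mesenchymal filament gene Vim were higher by 2.08 ± 0.08 and 1.31 ± 0.05 log2. All 16 macrophage and Kupffer cell markers were higher (adjusted p = 5.0e-05, and adjusted p = 0.29 with an estimated correlation), Cd68 at 72.2 ± 1.23 against 22.1 ± 1.81 CPM and C1qc at 214 ± 4.06 against 95.4 ± 2.57 CPM. All 11 monocyte and neutrophil markers were higher (adjusted p = 0.0014, and adjusted p = 0.16 with an estimated correlation; Itgam 2.10 ± 0.14 log2). 13 of 21 endotoxin response genes were higher (adjusted p = 0.017, and adjusted p = 0.22 with an estimated correlation): the co-receptor Cd14 stood at 96.4 ± 2.000 against 7.505 ± 0.497 CPM. Of single genes, the siderophore-binding Lcn2 was higher by 3.76 ± 0.09 log2, Sprr1a (chromosome 3, 92483952 to 92485895, minus strand) by 4.72 ± 0.20, Slc7a11 by 4.14 ± 0.12 and the metallothionein Mt2 by 4.09 ± 0.08. When adjusted over the list alone, 1 lipoprotein gene was higher, 8 male-biased genes were lower, and the other counts did not change.

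Of 22 lists called, the lipid synthesis, bile acid, lipoprotein, fatty acid oxidation, pericentral and matrix lists held with an estimated correlation; 3 more rose and 5 more fell (adjusted p of at least 0.062 with an estimated correlation). Rescaling by the median of gene ratios shifted the median of all genes by -0.27 log2 and the share of called genes that were higher from 79.3% to 49.4%. After averaging the close libraries, 96 genes were higher and 67 lower, with 11 of the 31 named here among them. The simulation with no group effect called 3443 genes (490 by at least 2-fold).

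Under GW3965 the liver of Villin-Cre mice also differed from that of floxed mice. Bile acid, pericentral and lipoprotein genes were lower in Villin-Cre than in floxed mice and matrix genes higher. Cyp8b1 (chromosome 9, 121914356 to 121916305, minus strand) stood at 8.86 ± 0.743 against 513 ± 163 CPM, Cyp7a1 at 14.3 ± 1.36 against 257 ± 113 CPM and Slc10a1 at 44.5 ± 0.671 against 407 ± 29.1 CPM. Abca1 was lower (-0.31 ± 0.04 log2, adjusted p = 6.9e-06; adjusted p = 0.4 with the close libraries averaged). In all, 7162 genes were higher and 2636 lower, 1347 and 680 by at least 2-fold.

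15 of 20 bile acid genes were lower and 3 higher (median -1.10, adjusted p = 1.3e-11). 21 of 25 cholesterol synthesis and uptake genes were lower (adjusted p = 1.8e-09, and adjusted p = 0.3 with an estimated correlation), Stard4 at -0.69 ± 0.09 log2 and Ebp at 83.7 ± 2.53 against 173 ± 46.6 CPM. 12 of 19 lipoprotein genes were lower and 3 higher (adjusted p = 6.5e-06), Lipc at -1.09 ± 0.05 and Apoa2 at -1.12 ± 0.05 log2. 8 of 11 pericentral genes were lower and 1 higher (adjusted p = 4.5e-08). Glul stood at 257 ± 6.07 against 1195 ± 55.5 CPM, Cyp2e1 at 775 ± 6.47 against 4297 ± 272 CPM and Oat at 81.1 ± 4.28 against 518 ± 127 CPM. 14 of 24 fatty acid oxidation genes were lower and 6 higher (adjusted p = 2.9e-04), Cyp4a10 at -1.76 ± 0.04 log2. 7 of 9 male-biased genes were lower (adjusted p = 4.5e-06, and adjusted p = 0.26 with an estimated correlation), Cyp4a12a at -2.96 ± 0.21 and Elovl3 at -5.50 ± 0.45 log2. LXR targets went both ways, 7 higher and 8 lower of 20 (adjusted p = 0.27), with a test statistic pointing down beside a median of 0.05 and a mean of 0.11; Abcg1 stood at 54.3 ± 2.37 against 23.02 ± 1.32 CPM and Scd2 at 234 ± 6.499 against 81.4 ± 2.49 CPM.

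25 of 27 matrix genes were higher and none lower (adjusted p = 1.7e-09). Col4a1 stood at 397 ± 9.81 against 136 ± 10.8 CPM and Thbs1 at 37.3 ± 0.602 against 4.396 ± 0.465 CPM. 14 of 16 macrophage markers were higher (adjusted p = 0.0026, and adjusted p = 0.41 with an estimated correlation), Cd68 by 1.47 ± 0.11 log2. 12 of 17 unfolded protein and integrated stress response genes were higher and 1 lower (adjusted p = 0.011, and adjusted p = 0.27 with an estimated correlation). The transcription factor Atf3 stood at 53.7 ± 1.77 against 4.79 ± 2.35 CPM and the transcription factor Ddit3 at 31.8 ± 2.45 against 9.11 ± 0.554 CPM. Sprr1a was higher by 6.91 ± 0.20 and Slc7a11 by 6.75 ± 0.12 log2, and Car3 lower (-5.18 ± 0.06 log2). Adjusted over the list alone, 16 bile acid, 22 cholesterol and 8 male-biased genes were lower, with the other counts as given.

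Of 20 lists called, the bile acid, matrix, pericentral, lipoprotein, fatty acid oxidation and B and plasma cell lists held with an estimated correlation; 3 more rose and 5 more fell (adjusted p of at least 0.24 with an estimated correlation). The median of gene ratios shifted the median of all genes by -0.23 log2 and the share of called genes that were higher from 73.1% to 50.6%. When the close libraries were averaged, 1159 genes were higher and 431 lower, and 20 of the 24 genes named here passed. Simulated libraries with no group effect gave 2367 calls (321 by at least 2-fold).

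The last comparison set the response of floxed mice to GW3965 in the ileum against that in the liver. Of 19 LXR targets tested besides Abca1, 14 had a difference (ileum minus liver) above 0, 1 below it and 4 did not pass; no list test was run here. The difference was 2.16 ± 0.17 log2 for Abca1, 3.14 ± 0.16 for Mylip, 2.79 ± 0.17 for Abcg1, 2.44 ± 0.20 for Srebf1 and 2.15 ± 0.14 for Abcg5 (adjusted p of 4.2e-10, 2.3e-13, 4.5e-12, 1.0e-09 and 2.5e-11). Scd1 and Scd2, which rose in the ileum and fell in the liver, differed by 3.81 ± 0.08 and 5.04 ± 0.25 log2. Apoe went the other way, at -0.65 ± 0.10 log2. Nr1h3, Pltp, Apoc2 and Arl4c did not pass (-0.01 ± 0.11, -0.07 ± 0.13, 0.77 ± 0.52 and 0.80 ± 0.39 log2, adjusted p of 0.97, 0.73, 0.29 and 0.13). Without the ileal library apart, Arl4c passed at 1.38 log2 (adjusted p = 6.9e-06) and Apoc2 lay at -0.02 log2. Of 16322 genes tested in both tissues, 2474 had a difference above 0 and 2279 below it, 704 and 538 of them of at least 2-fold. Large differences above 0 included the cystine importer Slc7a11 (5.65 ± 0.50 log2) and Cyp2d26 (3.71 ± 0.10 log2; chromosome 15, 82790101 to 82794294, minus strand), and those below 0 Tgtp1 (-3.63 ± 0.30 log2) and Gata4 (-2.96 ± 0.23 log2). Abca1 went from 57.2 ± 2.83 to 372 ± 105 CPM in the ileum and from 335 ± 7.81 to 470.2 ± 8.03 CPM in the liver. After averaging the close libraries, Cyp2d26 was the only gene past the threshold (adjusted p = 0.039), with 1538 genes at an unadjusted p under 0.05.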

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

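The results here differed between genotypes or tissues by a test of the difference itself; the tests of explanations were chosen after the results were seen, and the splits of the libraries before. In the ileum the response to GW3965 differed between genotypes in 6154 genes and 23 lists, in the liver in 3479 genes and 12 lists, and the response of floxed mice differed between ileum and liver in 4753 genes.

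The differences in the ileum, Villin-Cre minus floxed, were -1.73 log2 for Abca1, -2.14 for Srebf1, -1.83 for Abcg1, -0.96 for Abcg5, -0.75 for Scd1, -2.98 for Gzmb, -2.20 for Cd8a, -1.84 for Acta2, -2.10 for Nos1 and -2.06 for Reg3g. They were 5.33 for Cyp2c55, 3.26 for Abcb1a, 5.27 for Lct, 1.85 for Fabp2, 0.85 for Cpt1a, 0.82 for Hspa5 and 4.19 for Gata4. In the liver they were 0.27 log2 for Abca1, 2.99 for Scd2, 2.89 for Scd1, 1.52 for Fads2, 2.43 for Cdc20, 2.12 for Mki67, 1.02 for Lpl, 0.59 for Abcg1, 0.91 for Sparc and 1.15 for Kdr, and -2.19 for Slc1a2, -1.40 for Glul, -1.34 for Cyp2e1, -1.59 for Ifit1 and -1.95 for Nr0b2. Between tissues, ileum minus liver, they were 2.16 log2 for Abca1, 3.71 for Cyp2d26, 5.04 for Scd2, 3.81 for Scd1, 5.65 for Slc7a11, 3.14 for Mylip, 2.79 for Abcg1, 2.44 for Srebf1 and 2.15 for Abcg5, and -2.96 for Gata4, -3.63 for Tgtp1 and -0.65 for Apoe.

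The rise of LXR target genes with GW3965 in floxed ileum came with a rise of enterocyte markers, so a larger share of epithelium may have raised both. Against that as the whole cause, the LXR target median of the interaction was -0.91 log2 while the enterocyte median was 0.44, on opposite sides (adjusted p of 0.013 and 0.01 with an estimated correlation). A more distal position of the sampled segment stays open: the LXR target median with GW3965 in Villin-Cre mice was 0.0914, but Gata4, which marks the proximal bowel, did not fall there. Between genotypes given vehicle Gata4 did differ, at -2.58 ± 0.14 log2, but LXR targets went both ways (median -0.10, adjusted p = 0.72), the ileal bile acid list did not pass (adjusted p = 0.38) and the genotype differed as well, so this does not decide. The design names a biological explanation, an action of GW3965 on LXR that differs between genotypes, which was not tested apart from position and RNA source.

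Other splits of the same libraries were tried for each count. For the ileal interaction, 1 of 100 splits gave as many genes (highest other split 3555) and 7 of 100 as many lists (highest 24). These splits mixed the libraries of all 4 groups of the tissue. The differences by genotype and by treatment then enter the spread, so the splits cannot exclude chance for an interaction. For the liver interaction it was 3 of 100 for genes (highest 3899) and 58 of 100 for lists (highest 23), and for the tissue difference 2 of 100 (highest 6337), with the same condition for genes. The close libraries may share a source, and too few sources remain to test chance with the source as the unit. For the comparisons of 2 groups only 10 splits exist, too few for a share under 0.05. The real split was the only 1 of the 10 splits to call as many genes, with 0 genes in the highest other, in all 8 comparisons. The lists called in the real and the highest other split were 25 and 19, 17 and 16, 17 and 10 and 22 and 16 in the ileum (GW3965 in floxed, GW3965 in Villin-Cre, genotype with vehicle, genotype with GW3965), and 17 and 16, 23 and 7, 22 and 19 and 20 and 15 in the liver.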

How the results depend on the processing

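Averaging, voom, the deposited log2 values, a pseudocount of 2 and the list test on fold changes were chosen after seeing the data. With the close libraries averaged to 1, the genes past the threshold were 192, 1461, 21, 1231 and 14 in the ileum (GW3965 in floxed, GW3965 in Villin-Cre, genotype with vehicle, genotype with GW3965, interaction), 5, 0, 163, 1590 and 0 in the liver and 1 between tissues; this leaves 5 units in a tissue and 1 residual degree of freedom, from the 2 units of floxed GW3965, with 1 unit against 1 for GW3965 in Villin-Cre mice and genotype with vehicle. The GW3965 effect on liver Abca1 in floxed mice was then 0.49 log2 (adjusted p = 0.691). For GW3965 in floxed liver, 3458 genes passed with only the groups compared in the fit and 2673 with an additive model, and for GW3965 in Villin-Cre liver 4818 with only the groups compared; the cause was not tested. The additive model, which averages both genotypes, gave -0.53 log2 for Scd1 and -0.11 for Fads2 there. An estimated correlation brought the lists called to 8, 5, 2, 3 and 8 in the ileum and 3, 6, 6, 6 and 1 in the liver. Fry called 30 lists for GW3965 in Villin-Cre ileum, and a list test on fold changes 19 for the liver interaction. For GW3965 in Villin-Cre liver, leaving out any of 6 libraries gave 1084 to 1286 genes in place of 2081. For the liver interaction it gave 2673 to 5718 genes and 12 to 19 lists, both highest without the library apart. No other count moved by over 1.5 times in 84 refits for genes and 72 for lists. Of 2064 refits for named genes 2063 kept their side of the threshold, with no called gene reversed. The other, Arl4c in the tissue difference, passed without the ileal library apart. Close libraries stayed in each fit, so spread between sources was not tested. Over 296 combinations of a named gene and a comparison, 295 stayed on their side with median-of-ratios size factors, 292 with voom, 128 with the close libraries averaged (the other 168 no longer past the threshold, in the same direction) and all with the deposited log2 values, a pseudocount of 2, no filter or the replicate block. With only the groups compared, all 264 tried did. With the additive model 210 of 248 did, 34 were no longer past the threshold, 2 newly past it and 2 reversed. The counts of genes and lists moved by under 1.5 times with size factors, and those of genes with no filter, voom and the changed pseudocounts.

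Replicate numbers do not pair the libraries: deviations from the group means of same-numbered libraries correlated at -0.040 to 0.055 in the ileum and -0.026 to 0.031 in the liver. With the replicate block, 18 lists in place of 17 were called for genotype with vehicle in the ileum. For genotype with GW3965 in the liver, it was 21 in place of 20. A DESeq2 fit, planned for read counts, was not run, since log2 values were deposited. Depth did not limit the calls of 2-fold changes in simulated libraries. A change of 1.5-fold was recovered in 65.7 to 98.5% of genes of at least 5 CPM, depending on the contrast.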

Other observations

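Tests of the patterns below were chosen after the results were seen, except the search for shared sequence and the simulation with no group effect; Igha and Jchain were chosen after their values were seen. Gut hormone genes rose with GW3965 in floxed ileum: 6 of 13 enteroendocrine markers rose and 1 fell (adjusted p = 8.0e-04, and adjusted p = 0.12 with an estimated correlation). Neurotensin (Nts) went from 12.3 ± 1.85 to 63.9 ± 9.84 CPM, the satiety peptide Pyy from 10.8 ± 0.905 to 53.2 ± 12.3 CPM and secretin (Sct) by 1.68 ± 0.15 log2. Nts and Pyy were also higher in Villin-Cre than in floxed mice given vehicle, by 1.27 ± 0.12 and 1.39 ± 0.12 log2, but Chgb was lower (-0.73 ± 0.11 log2) and the list did not pass (4 higher, 4 lower, adjusted p = 0.1). Genes of the unfolded protein response fell in floxed ileum, 11 of 17 with 3 higher (adjusted p = 0.0042), the chaperones Hspa5 at -0.73 ± 0.05 and Manf at -0.94 ± 0.07 log2. All 13 genes encoded in mitochondria fell there (adjusted p = 1.8e-07, and 0.14 with an estimated correlation). All 13 lay above 0 in the interaction (adjusted p = 1.1e-07, and 0.21 likewise). In Villin-Cre ileum, 12 of 17 circadian clock genes rose with GW3965 and 5 fell (adjusted p = 0.0014, and adjusted p = 0.21 with an estimated correlation). Per3 went from 13.98 ± 2.31 to 123 ± 1.77 CPM, Per2 by 2.18 ± 0.12 and Nr1d1 by 1.10 ± 0.06 log2, while Nfil3 went from 28.9 ± 0.826 to 2.95 ± 0.306 CPM. Igha and Jchain, of secreted immunoglobulin A, fell with GW3965 (-1.50 ± 0.05 and -1.06 ± 0.07 log2 in floxed, -1.43 ± 0.05 and -1.33 ± 0.07 log2 in Villin-Cre mice). Their B and plasma cell list did not pass (adjusted p of 0.53 and 0.095).

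In the liver, antigen presentation genes were higher in Villin-Cre than in floxed mice. Of 9 MHC class II genes 7 were higher and 1 lower with vehicle (adjusted p = 0.035, and adjusted p = 0.41 with an estimated correlation), with Cd74 at 315 ± 4.300 against 120.1 ± 0.887 CPM and H2-Aa 1.30 ± 0.10 log2 higher. With GW3965 7 were higher and 0 lower (adjusted p = 0.011, and adjusted p = 0.32 with an estimated correlation). All 12 endothelial markers were higher in Villin-Cre liver with GW3965 (adjusted p = 3.9e-04, and adjusted p = 0.26 with an estimated correlation), the sinusoidal receptor Lyve1 by 2.66 ± 0.16 log2. B and plasma cell markers were lower in 6 of 15 cases and higher in 0 (adjusted p = 3.9e-04). Adjusted over the list alone, the counts of these ileal and liver lists did not change.

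In both tissues the libraries of a group were nearly identical apart from 1 library of floxed mice given GW3965. Repeat libraries of a shared RNA source may be the reason. Immunoglobulin V segments, which differ between animals, had a variance of at most 3.74 times Poisson in close ileal pairs, against 51.8 to 54.9 for the library apart and 43.3 to 123 between groups. How much of the group differences is spread between sources cannot be told apart in this design: simulated libraries with that spread and no group effect gave 2097 to 3443 called genes over the 10 contrasts within a tissue, such as 2992 against 9799 for GW3965 in Villin-Cre ileum, 3443 against 9951 for genotype with vehicle in the liver and 2752 against 3479 for the liver interaction. For GW3965 in Villin-Cre liver they gave more than the data, 3437 against 2081. With the close libraries averaged, the same simulations gave 0 to 6 genes.

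A set of 14 ileal genes at 10 CPM or more in floxed mice given vehicle was at least 8-fold lower in Villin-Cre mice given vehicle, and 11 of them had near-equal ratios of the close pair of floxed mice given GW3965 to floxed vehicle. Ffar2 stood at 1453 CPM in floxed mice given vehicle, 7649 in the close pair given GW3965 and 63.5 in the library apart. Villin-Cre mice had 20.3 with vehicle and 12.6 with GW3965. Elmod2, also of the 11, stood at 191.8, 934, 27.2, 19.8 and 28.3 CPM, so not all 11 kept the ratios in the other groups. The log2 ratio of the close pair to floxed vehicle was 2.00 to 2.51 in those 11 genes, with an SD of 0.153 against 0.382 in 3717 other genes higher there, as a single source of their reads in those libraries may give; the other 3 genes (Mt2, Plb1 and Pla2g2a), with a median of -1.33, argue against it for themselves. Neutrophils or enteroendocrine cells as the source of Ffar2 are argued against by the vehicle groups, where Ffar2 fell by 6.13 log2 from floxed to Villin-Cre, the list medians lay at -0.22 and -0.03 and no member lay below -1.06; shared sequence is by 0 of 14 genes sharing a word of 31 bases with another. Whether the animals, the sampled segment or the library preparation brought these transcripts was not tested.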
